A study of Homo sapiens with 9 samples.

How the data were processed

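Polyadenylated RNA of 3 human neuroblastoma cell lines was sequenced: Kelly and BE(2)C, in which MYCN is amplified, and SH-SY5Y, in which it is not. Each line had 3 libraries, 9 in all, from untreated cells. The labels number the libraries 1 to 3 within a line and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was taken from cells at partial confluence and made into libraries with a NEBNext Ultra kit.

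The deposited table holds log10 values, from the values themselves log10(TPM + 1): back-transformed, they sum to between 966592 and 980009 in each library, where another log base gives far smaller sums. The submitters' processing notes name HISAT 0.1.6, Salmon 0.3.2 and the GRCh38 build, with no role for each; how transcripts were combined into genes is not given in the sources used here. TPM values keep no depth, so the depth of each library is unknown and no counting interval or floor is given. Of the 19837 entries, 92 are ERCC spike-ins and 11 are reporter or selection markers. Another 28 carry a calendar date in place of a gene symbol; these stayed in the totals and out of the tests. Of 19706 usable gene symbols, 18678 matched GENCODE release 29 by symbol and 529 by an older or newer symbol, and 499 did not match. Coordinates are those of that annotation, on GRCh38. Every column of values was used, and the number of unused columns is 0.

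The spike-ins took 83.7% to 90.6% of the back-transformed total. Gene values were therefore rescaled to the TPM total over the gene entries alone, spike-ins and markers left out. They were then divided by a trimmed-mean factor computed without count weights (30% of log ratios and 5% of log levels trimmed at each end, genes at 1 or more in both libraries). The factors ran from 0.758 to 1.17. These values are called scaled TPM. The design fixed before the data were examined assumed counts and a count model with trimmed-mean factors. As the table holds no counts, its stated replacement was used: limma's trend method on log2(scaled TPM + 1) with all 9 libraries in 1 fit, no block, and genes at 1 or more in at least 3 libraries (13076 genes). A fold change on that scale understates the change of genes with low values. Benjamini-Hochberg adjusted p-values under 0.05 count as called, two-sided.

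The groups, the comparisons, the alternative settings except those named as later, 15 gene lists and the rule for named genes were also set before the data were examined. The rule names MYCN, MYC, LIN28A, LIN28B, HMGA2, IGF2BP1, ARID3B, DICER1 and ALK always; 2 genes that the rule names are not reported here. It adds, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with no overlap between the libraries of the lines and a mean of at least 10 in the higher line, leaving out unnamed identifiers, Y-linked genes and XIST. From each list it adds up to 4 called members with the largest absolute change and at least 10 in the higher line. The lists hold let-7 targets, microRNA biogenesis and silencing machinery, genes hosting let-7 loci, MYCN neighbours on 2p24, MYC-family targets in ribosome biogenesis and metabolism, adrenergic identity and mesenchymal identity. Others hold p53 targets, MHC class I antigen presentation, neuronal differentiation, proliferation, genes on 11q22-q25, genes on 3p21-p25, markers of other cell types (leukocyte, epithelial, hepatic and erythroid), and Schwann cell precursor and glial markers. They were written from general knowledge of the field. Members under the filter were not tested. This left 9 of 20 MHC class I genes, 24 of 38 mesenchymal genes, 6 of 12 glial markers and 4 of 14 markers of other cell types. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 42 tests (14 lists in 3 comparisons); camera with an estimated correlation and fry were run beside it. For 11q22-q25 the estimate was 0.0059, under the preset, yet its unadjusted camera p in BE(2)C vs SH-SY5Y rose from 0.0012 to 0.0139. A call lost with an estimated correlation therefore need not mean that the members were correlated above the preset. The list of genes hosting let-7 loci had only 2 members in the table and took no set test.

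Since Kelly and BE(2)C were compared with the same SH-SY5Y libraries, genes called in both were set beside 20 simulations of unchanged groups and beside the overlap of independent lists. Spike-ins with a mean of at least 10 deposited TPM (61) were tested with limma on their deposited values. Gene positions were grouped into windows of 10 Mb with at least 20 tested genes. Each window's median log2 fold change, less that of all genes, was set against 10000 random gene sets of the same size, and the number of windows passing against 20 shuffles of the genes over positions.

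The fit was tested on simulated data with 200 changed genes. All 9 libraries took the SH-SY5Y means of the genes, with independent normal noise of the fitted spread. For BE(2)C against SH-SY5Y, with 12327 genes in the fit, 46.3% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold were recovered, with 9 false calls. For Kelly against SH-SY5Y, with 12321 genes, the shares were 43.3%, 76.1% and 97.0%, with 10 false calls. In the real comparisons most genes were called, and the spike-in difference of Kelly was not simulated. These false calls therefore do not measure those of the real comparisons.

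The alternatives covered other scalings, filters, pseudocounts and thresholds, fits on 2 lines, the replicate number as a block, and each library left out in turn. Values as deposited kept the filter and pseudocount of 1, although genes held only 9.34% to 16.2% of their total. Both therefore weighed more, and 10279 genes were tested. That setting thus changes more than the scaling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.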

Results

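The data are RNA levels in 3 human neuroblastoma cell lines, 3 libraries each. Kelly and BE(2)C carry amplified MYCN, the oncogene whose copy number marks high-risk disease, and SH-SY5Y does not; the series title names let-7, the microRNA family that represses MYCN, LIN28B and other growth genes. The comparisons ask how the transcriptomes of the amplified lines differ from that of the non-amplified line and from each other. With a single non-amplified line, MYCN status and the identity of the line cannot be told apart. Genes made up 10.4 ± 0.950% of the back-transformed total in Kelly (SD, n = 3), 14.4 ± 1.14% in BE(2)C and 15.7 ± 0.504% in SH-SY5Y, and nearly all of the rest was ERCC spike-in RNA, the synthetic transcripts added to each sample. Mitochondrial genes took 30.6 ± 5.52% of the gene total in BE(2)C, 17.6 ± 1.87% in Kelly and 17.7 ± 0.455% in SH-SY5Y. The depth of the libraries is unknown. Several genes used by every cell had implausibly low values: HSPA8, a constitutive chaperone, had a share of the gene total on the TPM scale of 2.01 ± 1.36 in Kelly, 9.70 ± 3.21 in BE(2)C and 4.57 ± 1.12 in SH-SY5Y. TUBB, a tubulin gene, stood at 30.9 ± 0.396 in Kelly, 20.5 ± 1.65 in BE(2)C and 0.262 ± 0.241 in SH-SY5Y on that scale. Comparisons of levels between genes are therefore uncertain, and a fold change between lines can also reflect which of a gene's transcripts its value holds. Values of 0 are given as listed.

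The spike-ins set Kelly apart from the other lines. Over the 61 abundant spike-ins, the SD of the log2 ratio between libraries was 0.058 to 0.099 for the 9 pairs of the same line and 0.058 to 0.096 for the 9 pairs of BE(2)C with SH-SY5Y. It was 0.304 to 0.370 for the 18 pairs of Kelly with another line. limma called 52 of the 61 between Kelly and SH-SY5Y and 54 between Kelly and BE(2)C, against 0 between BE(2)C and SH-SY5Y. The values were centred on each library's spike-in median, which left most Kelly ratios below 0. An offset common to the spike-ins thus enters the calls, the shifts and the limits drawn from them, but not the SDs. The labels name no batch. The largest shift of a spike-in was 1.38 on the log2 scale against SH-SY5Y and 1.2 against BE(2)C. For Kelly changes within that size, a technical difference of the libraries and the line itself cannot be separated. Larger changes, such as that of MYCN against SH-SY5Y, exceed what the spike-ins showed.

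**Figure D1:**
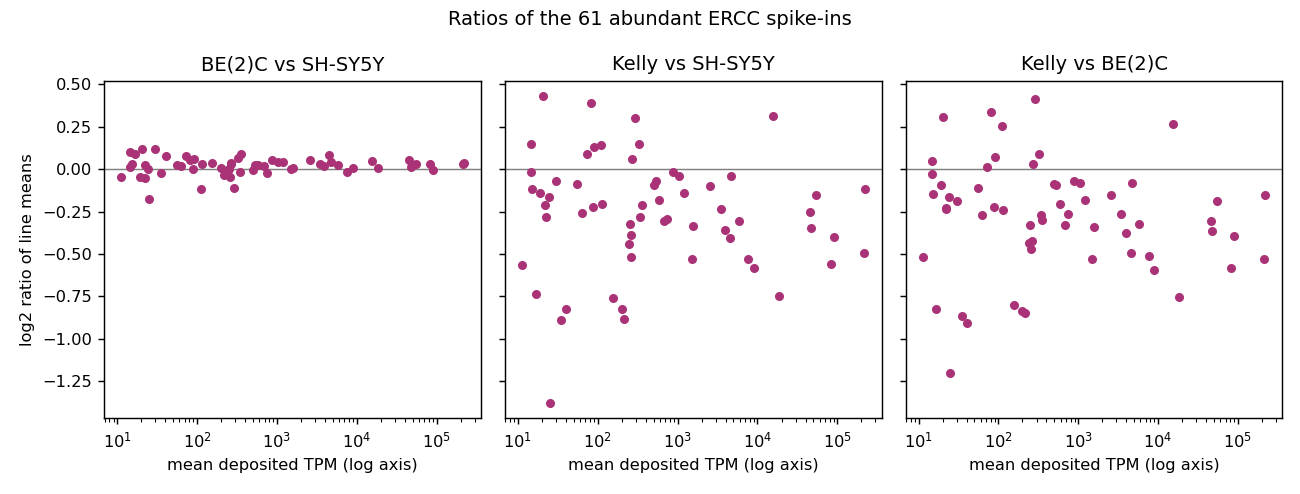
Log2 ratio of line means (vertical axis) against mean deposited TPM (log axis) for the 61 abundant ERCC spike-ins, 1 point each, in the 3 comparisons. Values were centred on each library's spike-in median. The SD of the ratios was 0.052 in BE(2)C vs SH-SY5Y, 0.340 in Kelly vs SH-SY5Y and 0.326 in Kelly vs BE(2)C.

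BE(2)C differed from SH-SY5Y in genes of the MYC family and of the let-7 axis. MYCN stood at 6050 ± 1090 scaled TPM in BE(2)C and 27.3 ± 1.01 in SH-SY5Y (SD, n = 3), a log2 fold change of 7.73 ± 0.12 (SE; limma, adjusted p = 6.4e-10). MYC, its close relative, was lower in BE(2)C, at 0.504 ± 0.175 against 90.4 ± 0.950 (log2 fold change -5.93 ± 0.16). LIN28B, an RNA-binding protein that blocks the maturation of let-7, was at 93.9 ± 7.70 in BE(2)C and 9.64 ± 0.537 in SH-SY5Y (3.16 ± 0.09). IGF2BP1, an oncofetal RNA-binding protein and let-7 target, was at 111 ± 4.41 against 0.137 ± 0.0417 (6.62 ± 0.08). DICER1, which cuts microRNA precursors, was higher by 0.93 ± 0.08 on the log2 scale. The receptor kinase gene ALK was lower in BE(2)C, at 15.4 ± 1.81 (-2.48 ± 0.09). HMGA2 (0.72 ± 0.32, adjusted p = 0.0833) and ARID3B (0.11 ± 0.10, adjusted p = 0.374) did not pass. ARID3B was lower with library totals only (-0.33, adjusted p = 0.0218), and HMGA2 passed without BE(2)C replicate 2 (adjusted p = 0.0320) and with quantile normalization (1.09, adjusted p = 0.0143). LIN28A, at 0.211 ± 0.147 and 0.328 ± 0.147, was under the filter.

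Beyond MYCN, the genes highest in BE(2)C against SH-SY5Y included ASS1, a synthetic enzyme of the urea cycle, at 672 ± 101 in BE(2)C and at 0, 0.0238 and 0 in the 3 SH-SY5Y libraries. IGF2, an insulin-like growth factor, was at 1610 ± 345 against 2.22 ± 0.369 (8.95 ± 0.16). PRPH, a neuronal intermediate filament, was higher by 8.74 ± 0.16 and MAB21L2 by 7.80 ± 0.11. The calcium-binding S100A11 (6.93 ± 0.26), the prostaglandin receptor gene PTGER2 (6.70 ± 0.32) and BCHE, which encodes butyrylcholinesterase (7.03 ± 0.12), completed the 8. The lowest were the protease inhibitor gene TFPI2 (-7.88 ± 0.23), the nuclear receptor gene RORB (-6.54 ± 0.15), the synaptic vesicle gene SV2C (-6.19 ± 0.14), OLFM2 (-6.10 ± 0.15) and ISLR2 (-5.94 ± 0.20). EFS and DUSP23 were listed at 0 in all 3 BE(2)C libraries, with means of 98.6 ± 6.44 and 87.9 ± 4.10 in SH-SY5Y. RPSAP58 (-7.03 ± 0.53) is a pseudogene of RPSA, and whether their reads were kept apart was not tested.

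By list, 25 of the 52 tested let-7 targets were higher in BE(2)C than in SH-SY5Y, 14 were lower and 13 did not pass (25 and 14 adjusted over the list alone), but with library totals only 15 were higher and 21 lower, and on values as deposited 14 and 20. MYCN, IGF2BP1 and IGDCC3 (5.13 ± 0.19) led those higher, and MYC those lower. The list stood above other genes (camera, adjusted p = 0.0271), but not with an estimated correlation (adjusted p = 0.442), with quantile normalization (adjusted p = 0.109) or without MYCN and the LIN28 genes (adjusted p = 0.0932). Of 45 MYC-family targets, 30 were higher and 5 lower (31 and 5 adjusted over the list alone; camera, adjusted p = 1.8e-05; adjusted p = 0.130 with an estimated correlation). Among them were the fatty acid carrier gene FABP5 (3.12 ± 0.10), the nucleolar NPM1 (2.00 ± 0.09) and the chaperonin HSPE1 (1.84 ± 0.12), while the glycolytic LDHA was lower (-2.36 ± 0.12), a value as doubtful as those of other abundant genes listed low. Of 30 proliferation genes, 22 were higher and 4 lower, with the same counts adjusted over the list alone (camera, adjusted p = 0.00176; adjusted p = 0.466 with an estimated correlation). Library totals only gave 7 and 8 (adjusted p = 0.105) and values as deposited 6 and 8 (adjusted p = 0.123), and the list did not pass with quantile normalization (adjusted p = 0.267). The mitotic genes PLK1 (1.39 ± 0.10), CCNB1 (1.29 ± 0.13) and AURKA (1.29 ± 0.16) were higher, and CCNE1, a cyclin of the entry into S phase, was lower (-1.25 ± 0.17).

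The chromosome-arm lists moved apart. Of 38 genes on 11q22-q25, 19 were higher in BE(2)C and 5 lower, the same adjusted over the list alone, against 8 and 11 on values as deposited (camera, adjusted p = 0.00459; adjusted p = 0.130 with an estimated correlation). Among those higher were the surface glycoprotein gene THY1 (1.97 ± 0.10) and the mitochondrial enzyme genes ACAT1 (1.87 ± 0.09), DLAT (1.43 ± 0.11) and SDHD (1.37 ± 0.12). Of 40 genes on 3p21-p25, 28 were lower and 4 higher (30 and 4 adjusted over the list alone; camera, adjusted p = 6.4e-04; adjusted p = 0.294 with an estimated correlation). Among those lower were the extracellular matrix gene FBLN2 (-3.23 ± 0.17), the DNA repair gene XPC (-1.65 ± 0.17), PBRM1 of a chromatin remodelling complex (-1.32 ± 0.15) and RBM6 (-1.55 ± 0.38). WDR82, a let-7 host gene on 3p, was lower by -0.89 ± 0.07, and HUWE1, the other host gene in the table, did not pass (-0.18 ± 0.09, adjusted p = 0.0972).

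The other 9 lists did not stand apart from other genes in BE(2)C against SH-SY5Y (camera, adjusted p from 0.248 to 0.690). Many members were called, but so were 59.4% of all tested genes. On values as deposited the adrenergic list (adjusted p = 0.0137) and MHC class I (0.0198) passed, as did glial markers with library totals only (0.0437). Calls adjusted over the list alone are given in brackets. The adrenergic list had 17 of 34 genes higher and 14 lower (17 and 15), including TH, the rate-limiting enzyme of catecholamine synthesis (5.11 ± 0.16), DLK1 (4.95 ± 0.18), INSM2 (4.54 ± 0.08) and, on the lower side, LMO1 (-4.42 ± 0.26). The mesenchymal list had 11 of 24 higher and 8 lower (12 and 8), with S100A6 higher (2.48 ± 0.15) and NOTCH2 (-4.56 ± 0.16), NOTCH3 (-3.10 ± 0.29) and COL1A2 (-2.51 ± 0.63) lower. Of 29 p53 targets, 11 were lower and 7 higher (11 and 7): PHLDA3 (-5.19 ± 0.14), TNFRSF10B (-4.31 ± 0.16), EDA2R (-3.79 ± 0.16) and GDF15 (-2.41 ± 0.25) were lowest. The microRNA machinery had 11 of 23 higher and 6 lower (11 and 6), with DDX17 up (1.49 ± 0.07) and AGO4 (-1.72 ± 0.13) and AGO3 (-1.04 ± 0.29) down. Neuronal genes split 14 to 13 among 32 (14 and 13), with GFRA2 (3.69 ± 0.26), SCG2 (2.49 ± 0.06) and SYT1 (2.37 ± 0.10) higher and ELAVL4 lower (-2.82 ± 0.08); their median was -0.16 while the test and the mean of 0.20 leaned upward. MHC class I genes had 5 of 9 higher and 2 lower (5 and 2), among them CALR (1.24 ± 0.07), ERAP1 (1.80 ± 0.27) and B2M (1.51 ± 0.26). MYCN neighbours on 2p24, a list that holds MYCN itself, had 4 of 12 higher and 5 lower (5 and 5). TRIB2 was up (1.49 ± 0.06) and VSNL1 (-3.22 ± 0.20) and GREB1 (-1.49 ± 0.14) were down. The list's median of -0.04 differed in sign from the test and the mean. Glial markers had 4 of 6 higher and 1 lower (4 and 1), SOX9 up (3.32 ± 0.21) and NGFR down (-3.37 ± 0.26), and markers of other cell types 2 of 4 higher and 0 lower (2 and 0).

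In all, 7764 of 13076 genes were called between BE(2)C and SH-SY5Y, 3744 higher in BE(2)C and 4020 lower (limma), and 1566 and 2172 of these differed at least 2-fold. The balance depends on the scaling: the share of calls that were higher was 48.2% here, 23.6% with library totals only, 36.3% with mitochondrial genes out of the total, and 18.2% on values as deposited, where the median over genes shifted by -0.435, -0.208 and -0.489. With library totals only, 15 let-7 targets were higher and 21 lower (median -0.09 against 0.37 here) and the median over 11q22-q25 turned to -0.07, while camera's direction against other genes held for every list that passed.

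**Figure D2:**
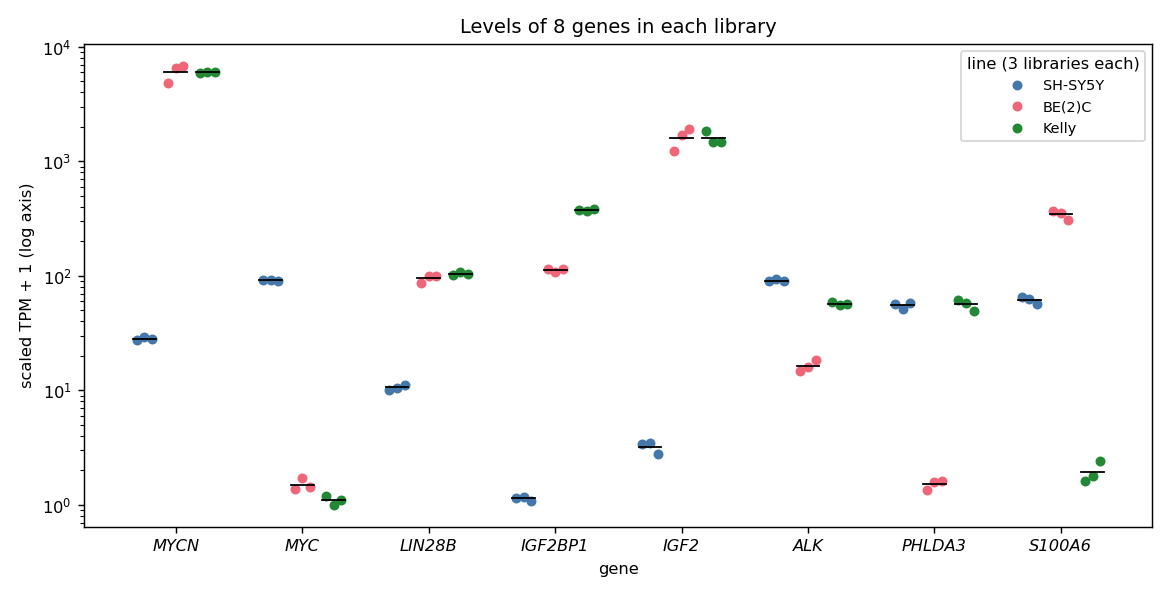
Scaled TPM + 1 (log axis) of 8 genes in each library, with 1 point per library, colours for the 3 lines and a bar at the mean of 3. MYCN, LIN28B, IGF2BP1 and IGF2 were higher in both amplified lines than in SH-SY5Y, MYC and ALK were lower, PHLDA3 was low in BE(2)C alone of the lines and S100A6 in Kelly alone.

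Kelly also differed from SH-SY5Y in genes of the MYC family and of the let-7 axis. MYCN was at 5970 ± 77.6 scaled TPM in Kelly (SD, n = 3; log2 fold change 7.72 ± 0.12, adjusted p = 6.04e-10). MYC was at 0.186, 0 and 0.102 in the 3 Kelly libraries, against 90.4 ± 0.950 in SH-SY5Y (log2 fold change -6.39 ± 0.16). LIN28B was at 104 ± 3.65 (3.30 ± 0.09) and IGF2BP1 at 374 ± 6.80 (8.37 ± 0.08). ARID3B, a let-7 target that encodes a DNA-binding protein, was higher in Kelly (1.39 ± 0.10), as was DICER1 (0.79 ± 0.08), whose call ended on values as deposited (0.08, adjusted p = 0.551). ALK was lower, at 56.3 ± 1.51 (-0.67 ± 0.09). HMGA2, a chromatin gene repressed by let-7, was near the filter of 1, at 2.24 ± 0.637 in Kelly and 0.555 ± 0.19 in SH-SY5Y. It passed (1.05 ± 0.32, adjusted p = 0.0214), but not without Kelly replicate 2 (adjusted p = 0.0731), Kelly replicate 3 (0.0530) or SH-SY5Y replicate 2 (0.0729).

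The highest genes in Kelly besides these were IGF2 (8.95 ± 0.16), TH at 480 ± 81.0 against 0.191 ± 0.176 (8.66 ± 0.16), PRPH (7.40 ± 0.16) and TRIM29 (7.0 ± 0.20). ASS1 stood at 238 ± 13.6 in Kelly and at 0, 0.0238 and 0 in SH-SY5Y. GAGE12J, a cancer-testis antigen gene of a family of near-identical copies and therefore uncertain, was at 125 ± 16.5 in Kelly and listed at 0 in all 6 libraries of the other lines. The lowest were C7, a complement component (-8.60 ± 0.13), TFPI2 (-6.75 ± 0.23), TSPYL5 (-6.44 ± 0.11), IGLON5 (-6.39 ± 0.20), DUSP23 (-6.34 ± 0.17) and NPTX2, a secreted synaptic protein (-6.31 ± 0.35). RPSAP58 was again low (-6.42 ± 0.53).

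Of the 52 let-7 targets, 30 were higher in Kelly than in SH-SY5Y, 11 lower and 11 not called (31 and 12 adjusted over the list alone; 16 and 19 on values as deposited), led by IGF2BP1, MYCN and IGDCC3 (6.06 ± 0.19). The list stood above other genes (camera, adjusted p = 0.00284; adjusted p = 0.313 with an estimated correlation). Of 45 MYC-family targets, 32 were higher and 3 lower, the same adjusted over the list alone, against 11 and 11 on values as deposited (adjusted p = 3.41e-06; adjusted p = 0.130 with an estimated correlation). Among those higher were FABP5 (2.72 ± 0.10), the ribosome assembly gene BOP1 (1.71 ± 0.06), NME1 (1.66 ± 0.14) and the folate enzyme gene MTHFD2 (1.44 ± 0.09). Of 30 proliferation genes, 20 were higher and 4 lower, the same adjusted over the list alone, against 4 and 11 on values as deposited (adjusted p = 0.00290, or 0.142 as deposited and 0.0591 with quantile normalization; adjusted p = 0.470 with an estimated correlation). Higher members included the replication licensing genes MCM5 (1.40 ± 0.06) and MCM2 (1.32 ± 0.07) and the kinases AURKA (1.52 ± 0.16) and AURKB (1.21 ± 0.16). MYCN neighbours on 2p24 had 8 of 12 higher and 1 lower, the same adjusted over the list alone, against 2 and 5 on values as deposited (adjusted p = 0.0271, or 0.0543 as deposited and 0.0863 with quantile normalization; adjusted p = 0.231 with an estimated correlation). This list includes MYCN itself and was not tested without it, so its call rests in part on the gene that defines the groups. Next to MYCN, FAM49A (2.08 ± 0.22), NBAS (0.89 ± 0.13) and the polyamine enzyme gene ODC1 (0.88 ± 0.07) were higher. On values as deposited NBAS (0.16, adjusted p = 0.382) and ODC1 (0.16, adjusted p = 0.277) did not pass. Genes on 11q22-q25 ran the other way from BE(2)C, with 23 of 38 lower in Kelly and 7 higher, the same adjusted over the list alone (adjusted p = 0.00176; adjusted p = 0.130 with an estimated correlation). ETS1 (-2.02 ± 0.17), MCAM (-1.47 ± 0.27) and CBL (-1.40 ± 0.09) were lower and PPP2R1B higher (1.42 ± 0.19).

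In Kelly against SH-SY5Y, 55.3% of all tested genes were called. The remaining 9 lists did not stand apart there (camera, adjusted p from 0.205 to 0.949), although the adrenergic list did on values as deposited (adjusted p = 0.00145). On those values the calls named here of BAX (0.40, adjusted p = 0.0620), CALR (0.13, 0.235), ALAS1 (0.23, 0.0903) and DUSP7 (0.21, 0.165) also ended. The adrenergic list had 17 of 34 higher and 14 lower (17 and 14 adjusted over the list alone), with TH, the vesicular monoamine transporter gene SLC18A2 (6.37 ± 0.22), DLK1 (5.55 ± 0.18) and INSM2 (5.13 ± 0.08) at the top. The mesenchymal list split 11 to 11 among 24 (11 and 11 over the list alone), with CD44 higher (3.08 ± 0.20) and S100A6 (-5.01 ± 0.15) and NOTCH2 (-4.56 ± 0.16) lower. COL1A2 was listed at 0 in all 3 Kelly libraries. The list's median of 0.28 differed in sign from the test and the mean of -0.34. The p53 list had 12 of 29 higher and 4 lower (12 and 4), with SESN2 (1.2 ± 0.16), BAX (1.15 ± 0.21) and AEN (1.11 ± 0.08) up and GDF15 down (-2.04 ± 0.25). The microRNA machinery had 9 of 23 higher and 5 lower (9 and 5), with TRIM71 (4.27 ± 0.18), DDX17 (1.87 ± 0.07) and TNRC6B (1.55 ± 0.11) up. Neuronal genes split 11 to 13 among 32 (12 and 13), the neurofilament gene NEFH (3.33 ± 0.10) and GFRA2 (3.84 ± 0.26) up and VGF (-5.65 ± 0.12) and ELAVL4 (-3.30 ± 0.08) down. Their median was 0.02, with a mean and test on the lower side. MHC class I genes split 2 to 2 among 9 (2 and 2), CALR up (0.85 ± 0.07) and PSME1 down (-1.08 ± 0.17), with a median of -0.39, a mean of -0.19 and a test on the higher side. Genes on 3p21-p25 had 12 of 40 lower and 8 higher (12 and 8), WDR82 (-1.02 ± 0.07) and RBM6 (-2.04 ± 0.38) down and ALAS1 (0.96 ± 0.10) and DUSP7 (0.95 ± 0.11) up. Glial markers had 3 of 6 higher and 1 lower (3 and 2), SOX9 up (4.20 ± 0.21) and NGFR down (-2.74 ± 0.26), and markers of other cell types 1 of 4 each way (1 and 1; median -0.24, mean 0.09, test on the lower side).

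In all, 7230 genes were called between Kelly and SH-SY5Y, 3673 higher in Kelly and 3557 lower (limma), with 1586 and 1750 of them at least 2-fold apart. Against the spike-ins, of which 5% differed by more than 1.77-fold in this comparison, 4111 called genes exceeded that size. The share of calls that were higher was 50.8%, against 41.5% with library totals only, 41.8% with mitochondrial genes out of the total and 12.1% on values as deposited. There the median over genes shifted by -0.133, -0.135 and -0.601 and the median of the let-7 list turned to -0.04.

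**Figure D3:**
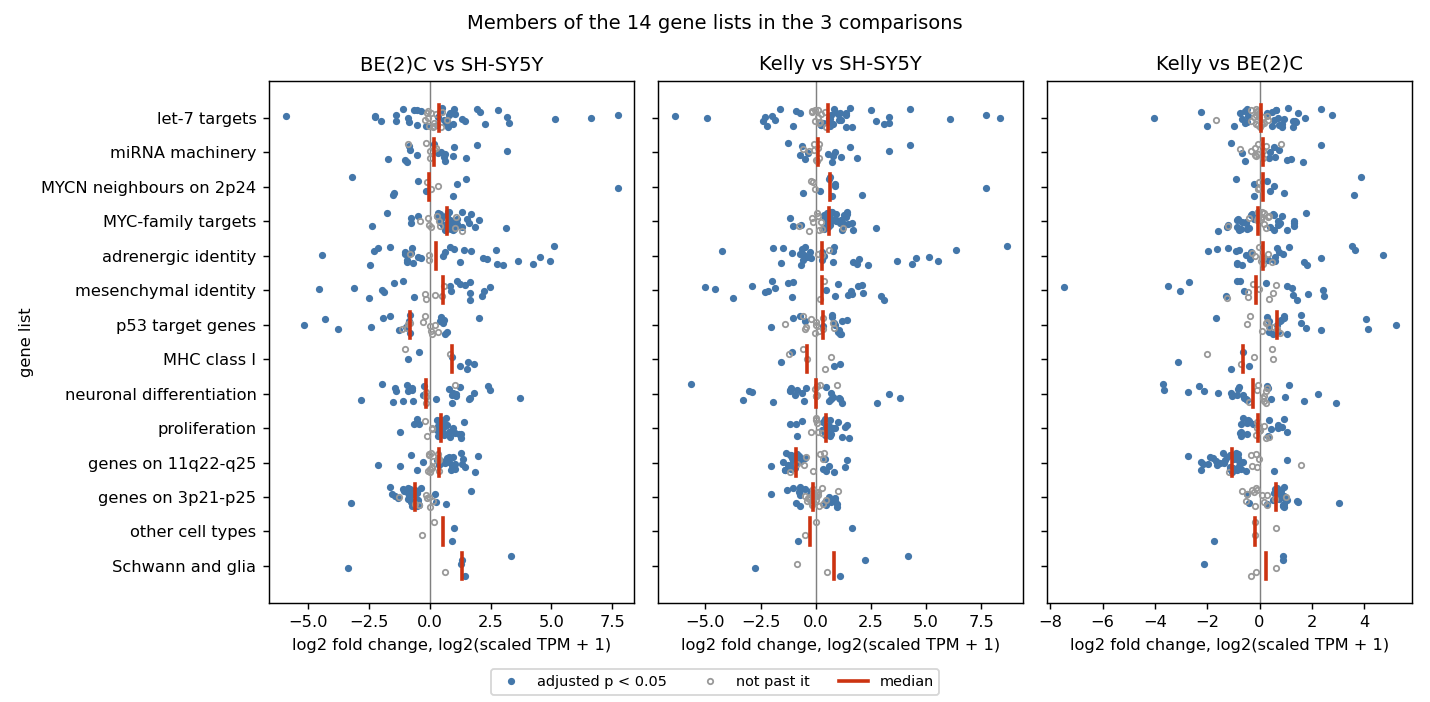
Log2 fold change on the log2(scaled TPM + 1) scale (horizontal axis) of each tested member of the 14 gene lists in the 3 comparisons, filled where the adjusted p was under 0.05, with a bar at the list's median. Genes on 11q22-q25 had medians of 0.37 in BE(2)C vs SH-SY5Y, -0.91 in Kelly vs SH-SY5Y and -1.04 in Kelly vs BE(2)C; with library totals only the median in BE(2)C vs SH-SY5Y turned to -0.07.

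Both amplified lines shared a large part of their difference from SH-SY5Y. MYCN (chromosome 2, 15940564 to 15947007), LIN28B (chromosome 6, 104936616 to 105083332) and IGF2BP1 (chromosome 17, 48997412 to 49055650) were among 2185 genes higher in both than in SH-SY5Y, and MYC (chromosome 8, 127735434 to 127741434) was among 2213 lower in both (GRCh38). At least 2-fold in both lines, 726 genes were higher and 976 lower, IGF2, PRPH, DLK1 and INSM2 among the higher and TFPI2 and C7 among the lower. Independent lists of these sizes would share 1052 and 1094 genes. Unchanged groups set against the same SH-SY5Y libraries shared 0.05 and 0 on average over 20 simulations. With no gene changed almost none can be called, so the simulations are no reference for lines that differ. A gene whose level is peculiar to SH-SY5Y counts in both comparisons. An overlap above that of independent lists therefore does not show a change common to the amplified lines. As 3 control libraries cannot be split into groups of 2, part of the excess may come from the shared libraries. The average of the amplified lines differed from SH-SY5Y in 7853 genes, 3851 higher and 4002 lower (limma). The balance depended on the scaling, with 2429 higher and 5582 lower with library totals only and 1029 and 6461 on values as deposited. On values as deposited the shared counts became 521 higher and 4679 lower, and with library totals only 1227 genes were higher. Above the 5% limit of the spike-ins in each comparison, 1218 were higher and 1462 lower in both.

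**Figure D4:**
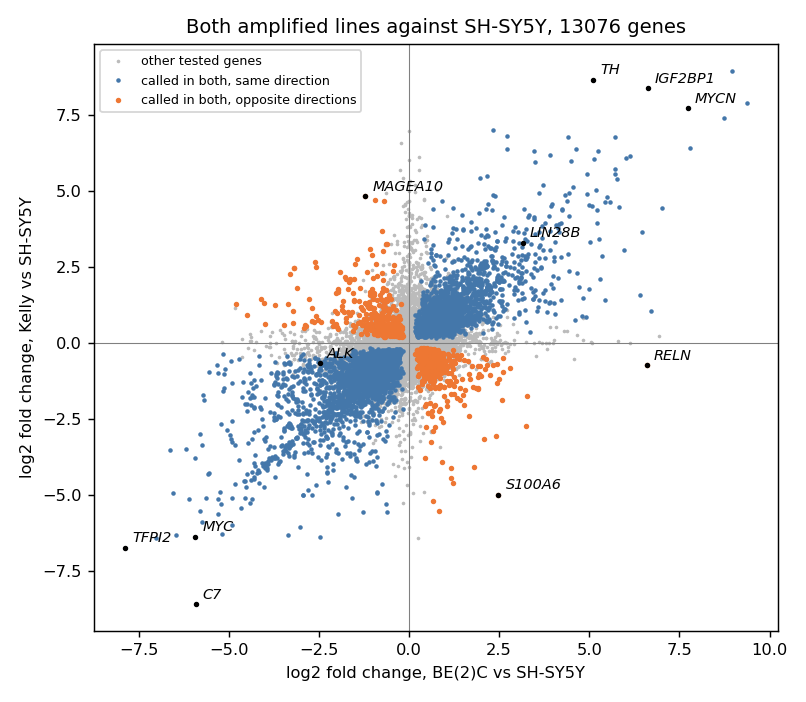
Log2 fold change of 13076 genes in Kelly vs SH-SY5Y (vertical axis) against BE(2)C vs SH-SY5Y (horizontal axis), 1 point per gene, coloured by whether both comparisons called the gene in the same or in opposite directions. MYCN lies at 7.73 and 7.72 and MYC at -5.93 and -6.39, while S100A6 lies at 2.48 and -5.01.

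The amplified lines also differed from each other, and the sign of their MYCN difference depended on the scaling. Kelly and BE(2)C held MYCN at 5970 ± 77.6 and 6050 ± 1090 (log2 fold change 0.00 ± 0.12, adjusted p = 0.991). Without BE(2)C replicate 1, the lowest of its line, Kelly was lower (-0.16, adjusted p = 0.0358). With library totals only (0.32, adjusted p = 0.0240) and with quantile normalization (0.62, adjusted p = 0.00113) Kelly was higher. LIN28B (0.14 ± 0.09, adjusted p = 0.198) and DICER1 (-0.14 ± 0.08, adjusted p = 0.176) did not differ past the threshold, although LIN28B did with library totals only (0.46, adjusted p = 0.00330). Kelly had more IGF2BP1 (1.75 ± 0.08), ARID3B (1.28 ± 0.10) and ALK (1.81 ± 0.09) than BE(2)C. MYC, near 0 in both, passed (-0.45 ± 0.16, adjusted p = 0.0410), but not without Kelly replicate 2 (adjusted p = 0.114), Kelly replicate 3 (0.0792), BE(2)C replicate 2 (0.120) or BE(2)C replicate 3 (0.0539). Its call also ended with library totals only (0.0932), no filter (0.0548), a replicate block (0.0789) and values as deposited (0.586). HMGA2 did not pass (0.33 ± 0.32, adjusted p = 0.427), but without BE(2)C replicate 3 it did (0.72, adjusted p = 0.0328).

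Among the genes highest in Kelly against BE(2)C, GAGE12J, MAGEA1 and the serine protease gene PRSS21 stood at 125 ± 16.5, 111 ± 6.03 and 64.6 ± 12.5 in Kelly and were listed at 0 in all 3 BE(2)C libraries; MAGEA10 was at 80.3 ± 2.30 against 0.234 ± 0.0617 (6.04 ± 0.16). MAP7D2 was likewise listed at 0 in BE(2)C, against 67.5 ± 2.62 in Kelly. TTC9B (5.97 ± 0.46), FAM19A5 (5.96 ± 0.17) and the proteoglycan gene FMOD (5.83 ± 0.18) completed the 8 highest. The lowest in Kelly were the calcium-binding S100A6, at 0.937 ± 0.405 against 343 ± 33.6 (-7.49 ± 0.15), and the extracellular glycoprotein gene RELN (-7.33 ± 0.16). S100A11 (-6.71 ± 0.26), TSPYL5 (-6.70 ± 0.11), the transcription factor gene GATA4 (-6.37 ± 0.12) and the matrix gene EDIL3 (-5.99 ± 0.15) followed. IL13RA2 and ENPP2 were listed at 0 in all 3 Kelly libraries, with 70.3 ± 14.7 and 58.3 ± 9.91 in BE(2)C.

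Genes on 11q22-q25 were lower in Kelly than in BE(2)C in 29 of 38 cases and higher in 2, the same adjusted over the list alone, with a median log2 fold change of -1.04 (camera, adjusted p = 3.67e-09). This was the only list call that held with an estimated correlation (adjusted p = 0.0195). That estimate missed the threshold with library totals only (0.419), on values as deposited (0.667) and with a replicate block (0.157), and without Kelly replicate 1 (0.0521), 2 (0.0701) or 3 (0.0567) or SH-SY5Y replicate 1 (0.0708), 2 (0.0544) or 3 (0.0525). THY1 (-2.73 ± 0.10), the adhesion genes CADM1 (-2.25 ± 0.18) and MCAM (-2.24 ± 0.27) and HSPA8 (-2.18 ± 0.37) were lowest, HSPA8 being among the genes with implausibly low values. Genes on 3p21-p25 were higher in Kelly in 24 of 40 cases and lower in 2, the same adjusted over the list alone (adjusted p = 0.00252; adjusted p = 0.318 with an estimated correlation). FBLN2 (3.04 ± 0.17), MAPKAPK3 (1.48 ± 0.14), MKRN2 (1.45 ± 0.19) and NBEAL2 (1.06 ± 0.21) were among them. Of 29 p53 targets, 19 were higher in Kelly and 1 lower (20 and 1 adjusted over the list alone; adjusted p = 3.03e-04; adjusted p = 0.171 with an estimated correlation). PHLDA3, a repressor of AKT, was at 55.2 ± 6.19 in Kelly and 0.514 ± 0.147 in BE(2)C (5.21 ± 0.14); EDA2R (4.14 ± 0.16), the death receptor gene TNFRSF10B (4.08 ± 0.16) and CDKN1A, the cell-cycle inhibitor (2.34 ± 0.18), were higher too.

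The other 11 lists did not stand apart between Kelly and BE(2)C (camera, adjusted p from 0.116 to 0.793), where 52.5% of all tested genes were called. Of the let-7 targets, 20 were higher in Kelly and 11 lower, the same adjusted over the list alone (adjusted p = 0.483). NR6A1 (2.78 ± 0.18) and TRIM71 (2.34 ± 0.18) were up and the insulin receptor gene INSR (-4.04 ± 0.15) and RGS16 (-2.24 ± 0.10) were down. In brackets are the counts adjusted over the list alone. The MYC-family list split 14 to 17 of 45 (14 and 18; median -0.04, mean 0.01, test on the lower side), with TERT, the telomerase gene (1.79 ± 0.17), MYBBP1A (1.33 ± 0.10) and NOP56 (1.33 ± 0.20) up. APEX1 was lower (-1.61 ± 0.56), but its call ended without any of Kelly replicates 1 and 2 and BE(2)C replicates 1 and 3 (adjusted p = 0.119, 0.0834, 0.123 and 0.0554), with library totals only (0.0787) or with no filter (0.0590). The proliferation list split 8 to 12 of 30 (9 and 12), with CCNE1 (1.05 ± 0.17), TYMS (0.92 ± 0.10) and MCM2 (0.87 ± 0.07) up and CCNB2 down (-0.77 ± 0.12). The adrenergic list had 14 of 34 higher and 11 lower (15 and 11), with LMO1 (4.71 ± 0.26), SLC18A2 (3.66 ± 0.22), TH (3.55 ± 0.16) and INSM1 (2.37 ± 0.32) up. The mesenchymal list split 8 to 8 of 24 (9 and 9), with SNAI2 (-3.50 ± 0.36) and VIM (-2.70 ± 0.12) down and NES up (2.42 ± 0.05). Neuronal genes had 15 of 32 lower and 8 higher (16 and 9), with VGF (-3.68 ± 0.12), SCG2 (-3.67 ± 0.06) and NPY (-2.72 ± 0.38) down and CNTNAP2 up (2.92 ± 0.43). MHC class I genes had 4 of 9 lower and 0 higher (6 and 0), with B2M (-1.08 ± 0.26), PSME1 (-0.64 ± 0.17) and CALR (-0.39 ± 0.07). With library totals only PSME1 (-0.33, adjusted p = 0.162) and CALR (-0.07, adjusted p = 0.475) did not pass. The microRNA machinery had 9 of 23 higher and 3 lower (9 and 3), with AGO1 (1.67 ± 0.09) and AGO4 (1.22 ± 0.13) up and ZCCHC6 down (-1.10 ± 0.18). MYCN neighbours had 6 of 12 higher and 3 lower (6 and 3), with VSNL1 (3.89 ± 0.20) and FAM49A (3.60 ± 0.22) up. Glial markers had 2 of 6 higher, SOX9 among them (0.88 ± 0.21; adjusted p = 0.0724 with a pseudocount of 0.1), and 1 lower (2 and 1; median 0.25, mean -0.03, test on the higher side), and markers of other cell types 0 of 4 higher and 1 lower (0 and 1).

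In all, 6861 genes were called between Kelly and BE(2)C, 3647 higher in Kelly and 3214 lower (limma), with 1669 and 1247 at least 2-fold apart; 3617 exceeded 1.80-fold, the size that 5% of the spike-ins passed. The share that was higher was 53.2%, against 74.3% with library totals only (median shift 0.31) and 40.1% on values as deposited (median shift -0.13). Of the genes called in both comparisons with SH-SY5Y, 700 ran in opposite directions, 102 of them at least 2-fold each way.

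Fold changes were grouped along the chromosomes. Of 236 windows of 10 Mb, 73 had a median outside that of random gene sets in BE(2)C vs SH-SY5Y (30 higher, 43 lower), 41 in Kelly vs SH-SY5Y (21 and 20) and 101 in Kelly vs BE(2)C (55 and 46). At most 1 did in 20 shuffles of each (permutation test, Benjamini-Hochberg adjusted p under 0.05). The largest median in Kelly vs SH-SY5Y lay on chromosome 7 from 100000001 to 110000000, where 87 of 91 genes were below the overall median (window median -1.45). Its permutation p was 1e-04, the smallest the random sets can give (adjusted p = 0.00107), and the same window was at -1.05 against BE(2)C. On chromosome 11 from 120000001 to 130000000, within the reach of the 11q list, 36 of 45 genes were below the median in Kelly vs BE(2)C (window median -1.09) and 37 of 45 in Kelly vs SH-SY5Y (-0.85). On chromosome 3 from 1 to 10000000, 26 of 30 genes were below it in BE(2)C vs SH-SY5Y (-0.84, adjusted p = 0.00182). Windows were singled out for their size after the values were seen.

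**Figure D5:**
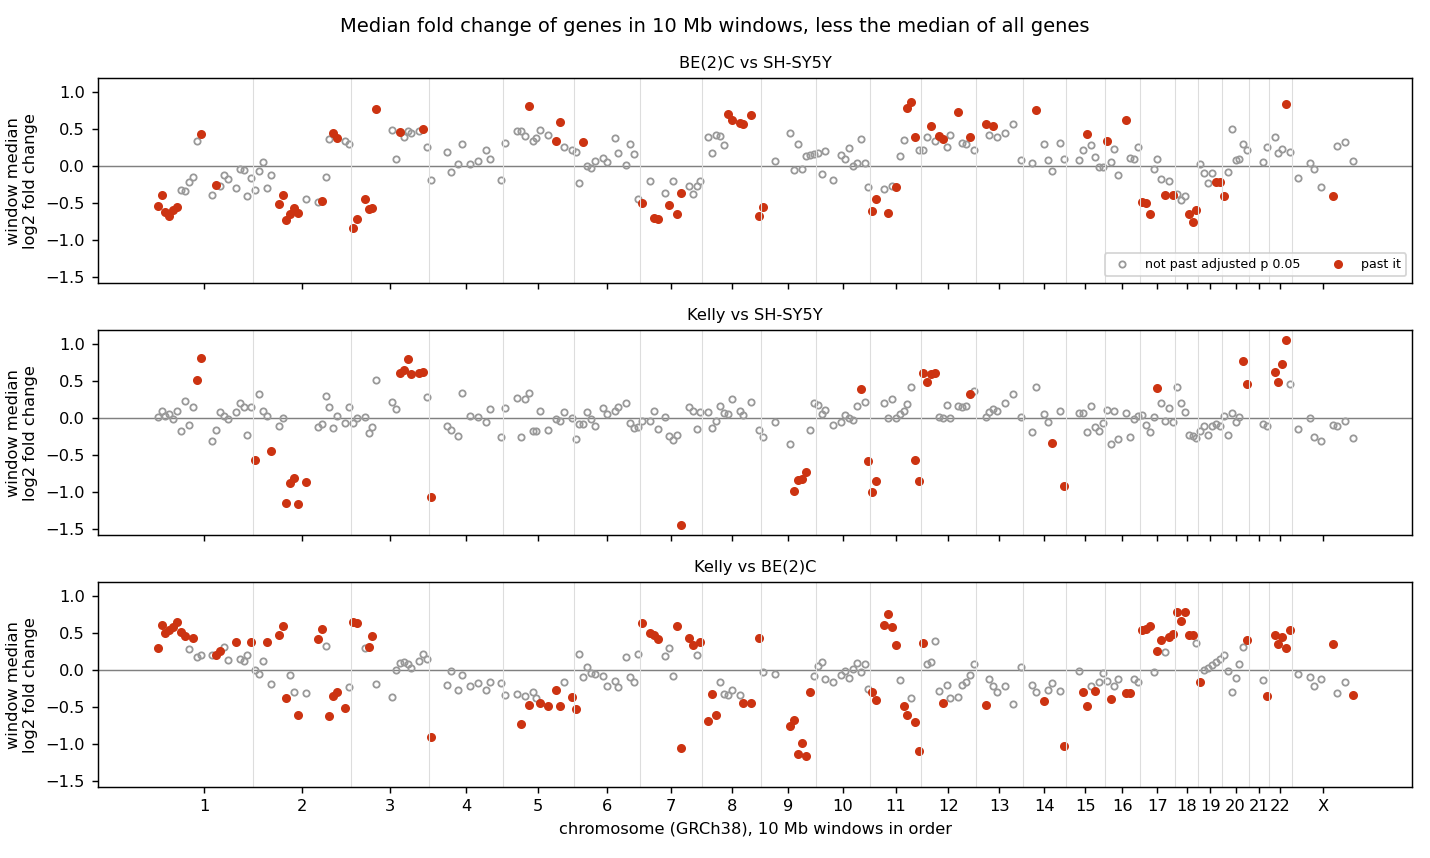
Median log2 fold change of the genes in each 10 Mb window, less the median of all genes (vertical axis), along the chromosomes in order (GRCh38), filled where the window passed an adjusted p of 0.05, in the 3 comparisons. Of 236 windows, 73, 41 and 101 passed.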

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

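The tests of the spike-in mixes and of the ampicillin-resistance marker were chosen after the results were seen. Those of other splits were planned. The bounds for GC content and length were written before those tests were run. They were not part of the design fixed before the data were examined, and they concern the spike-in pattern of Kelly seen in these data.

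Opposite directions against SH-SY5Y in Kelly and BE(2)C singled out 700 genes (limma). Among the named genes, those higher in Kelly than in BE(2)C, with their log2 fold changes, were MAGEA10 (6.04), VSNL1 (3.89), FAM49A (3.60), NR6A1 (2.78), NES (2.42), CDKN1A (2.34), AGO1 (1.67), MAPKAPK3 (1.48), MKRN2 (1.45), MYBBP1A (1.33) and TYMS (0.92). Those lower were S100A6 (-7.49), RELN (-7.33), GATA4 (-6.37), EDIL3 (-5.99), SCG2 (-3.67), THY1 (-2.73), VIM (-2.70), CADM1 (-2.25) and MCAM (-2.24). MAP7D2 was listed at 0 in BE(2)C and ENPP2 at 0 in Kelly, so their fitted values of 6.10 and -5.88 depend on the pseudocount. The values of MAGEA10, VSNL1, FAM49A, S100A6, RELN, GATA4 and EDIL3 also depend on it, as their means in the lower line were under 1. Lists that differed between Kelly and BE(2)C had medians of 0.69 for p53 targets, -1.04 for 11q22-q25 and 0.62 for 3p21-p25.

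The spike-ins, which should be alike in every library, singled out Kelly: 52 of 61 were called against SH-SY5Y and 54 against BE(2)C. These calls include the offset left by centring on library medians. A swap between the commercial mixes would give a 90th percentile of absolute log2 ratios of 1 or more, and the value was 0.800. Across genes, Spearman's rho of fold change with transcript length was at most 0.068 in size in the Kelly comparisons. Genes are not independent replicates, and most were called between these lines, which could hide such a trend. The lengths of the spike-ins themselves were not used, so a length-dependent difference is not excluded. With GC content rho was 0.131 in Kelly vs BE(2)C and -0.007 in Kelly vs SH-SY5Y, but -0.116 in BE(2)C vs SH-SY5Y, where 0 spike-ins were called. The larger values thus go with BE(2)C, not Kelly. The bound set for a GC-dependent difference was not reached and the bound against it was not met, so it stays open. The labels name no batch. For changes up to the largest spike-in shift, 1.38 on the log2 scale against SH-SY5Y and 1.2 against BE(2)C, a technical difference of the Kelly libraries cannot be told apart from the line itself.

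A marker for ampicillin resistance, which no human cell carries, stood at 170.9 deposited TPM on average over the 9 libraries. The coefficient of variation was 14.1% for its ratio to the spike-in total and 15.0% for its ratio to the gene total, where a constant ratio was taken as under 5%. Without Kelly replicate 1 they were 14.5% and 7.86%, and without BE(2)C replicate 2 they were 15.08% and 14.93%. Leaving out either library thus turned their order. An origin in the spike-in preparation and a signal that scales with cellular RNA could not be told apart. No biological explanation was tested.

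Other splits of the libraries bear on the counts of called genes. In fits on 2 lines, the real split called the most genes, 1 of the 10 splits in each comparison: 7674 for BE(2)C vs SH-SY5Y, 7346 for Kelly vs SH-SY5Y and 6279 for Kelly vs BE(2)C, with 0 as the highest other. With 10 splits a share under 0.05 cannot be reached. For SH-SY5Y against the amplified lines, the real split, with 4447 genes, was the only 1 of the 84 to give as many. Libraries of a line are not exchangeable with those of another, so this outcome does not test a random division of the libraries. BE(2)C against the other lines called 3794 and Kelly 2659, and splits that mixed libraries of a line called at most 1, so any line set apart gives many calls and the count does not single out MYCN status.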

How the results depend on the processing

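Chosen after the data were seen were the values as deposited, the total without mitochondrial genes, the genes with at most 3 transcripts, the fit without a variance trend and the spike-in limit. DESeq2 and limma-voom were not run, since they need counts. Library numbers did not pair: correlations of same-numbered libraries ran from -0.054 to 0.027, and 2 libraries correlated best with their own number. Of 2190 values of the 195 named results that passed, 2174 kept direction and call under other settings and 16 lost the call. Leaving out a library, 1699 of 1710 did and 11 lost it. Apart from the genes always named, these were picked from the same data as called genes with large changes. That choice favours a kept call, so the shares do not speak for the other called genes. Of 144 values of the 13 list tests that passed, 113 kept the call and 31 lost it under other settings of camera, and all 117 kept it with a library left out. Depth is unknown, so its limit on low values cannot be given. Except where a construction is named, the cause was not tested.

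Fewer genes tested explains the counts with at most 3 transcripts: 1835 for BE(2)C vs SH-SY5Y, 1766 for Kelly vs SH-SY5Y, 1663 for Kelly vs BE(2)C, 1907 for the average, 520 higher in both and 590 lower in both. A 2-fold minimum left 3738, 3336, 2916, 3148, 726 and 976. The spike-in limit left 4111 for Kelly vs SH-SY5Y and 3617 for Kelly vs BE(2)C, with 1218 higher and 1462 lower in both. Library totals only gave 1227 higher in both; values as deposited gave 521 higher and 4679 lower. The replicate block gave 7544, 6980, 6634 and 7635. With a library left out the counts ran from 6721 to 7773, 6146 to 7366, 6050 to 6659 and 6627 to 7712, with 1913 to 2154 higher and 1639 to 2176 lower in both.

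The let-7 list in BE(2)C vs SH-SY5Y ranged with camera from an adjusted p of 0.0161 (as deposited) to 0.442 (estimated correlation), with 0.109 under quantile normalization and 0.0932 without MYCN, LIN28A and LIN28B; leaving out a library gave 0.00703 to 0.0341. In Kelly vs SH-SY5Y it ranged from 1.46e-04 to 0.313, or 5.11e-04 to 0.00329, and in Kelly vs BE(2)C from 0.232 to 0.772. Fry asks whether the members moved on balance, not whether they moved more than other genes, so its values are no alternative to those of camera. Fry gave 2.64e-06, 1.37e-06 and 0.00705 in the 3 comparisons. With at most 3 transcripts the list kept its calls on 17 members (0.0197 and 0.00353), while other lists kept few members and none of their calls held; MYCN neighbours, MHC class I and other cell types had too few for a value.

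ARID3B in BE(2)C vs SH-SY5Y turned to -0.33 with library totals only, -0.36 as deposited and -0.10 without mitochondrial genes in the total. MYCN in Kelly vs BE(2)C was 0.32 with totals, 0.00 with RLE factors, 0.62 with quantile normalization and 0.07 without mitochondrial genes, and -0.16 to 0.09 with a library left out. DICER1 there was 0.18 with totals.

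Lists that did not pass and turned direction had these adjusted p-values. In Kelly vs SH-SY5Y the mesenchymal list gave 0.973 (totals), 0.840 (no filter), 0.955 (no mitochondrial genes), 0.822 (at most 3 transcripts) and 0.742 to 0.795 (an SH-SY5Y library left out). Other cell types gave 0.973, 0.943, 0.966, 0.954 (quantile), 0.967 (fry) and 0.752 to 0.982 (without Kelly replicate 2 or 3 or SH-SY5Y replicate 1 or 3). MHC class I gave 0.943 (no filter), 0.982 (pseudocount 0.1) and 0.879 to 0.998 (without BE(2)C replicate 3 or SH-SY5Y replicate 1 or 3). Over all fits with a library left out, whether the direction turned or held, the mesenchymal list ran from 0.725 to 0.849 and MHC class I from 0.759 to 0.998. Neuronal and 3p21-p25 genes gave 0.822 with at most 3 transcripts. In Kelly vs BE(2)C, MYC-family targets gave 0.614 (totals), 0.744 (quantile), 0.344 (fry) and 0.507 (at most 3 transcripts), proliferation 0.614 and 0.744, glial markers 0.953, 0.954 and 0.884 (no mitochondrial genes), and the mesenchymal list 0.609 (at most 3 transcripts). In BE(2)C vs SH-SY5Y the mesenchymal list gave 0.00362 with fry and, like p53 targets, 0.713 with at most 3 transcripts.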

Other observations

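The shares and ranks of MYCN were chosen after its values were seen. The bounds for ribosomal protein genes and chromosome windows were written before those tests were run. They were not part of the design fixed before the data were examined, and those for ribosomal protein genes concern the low values seen in these data.

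MYCN made up 58.3 ± 0.540% of the summed values of the 59 let-7 targets in the table in Kelly (SD, n = 3) and 58.6 ± 4.5% in BE(2)C, against 0.778 ± 0.027% in SH-SY5Y. It ranked between 2 and 3 among nuclear genes in the Kelly libraries, 2 in each BE(2)C library and 5267 to 5532 in SH-SY5Y. These shares and ranks compare genes with each other, which the low values of several abundant genes make uncertain.

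Genes used by every cell were low: FTH1, a ferritin chain, stood at 6.14 ± 4.8 on the TPM scale of the gene total in Kelly, 2.4 ± 1.4 in BE(2)C and 3.22 ± 1.1 in SH-SY5Y. Over 77 cytosolic ribosomal protein genes, from 0.279 to 5177, the level fell with the number of annotated transcripts (Spearman's rho -0.623, Pearson's r -0.491, permutation p = 1e-05, the smallest the permutations can give). The median was 1638 in the 41 genes with at most 9 transcripts and 221.3 in the 36 with more. Genes are not independent replicates. A value that holds only part of a gene's transcripts is a candidate explanation, while reads shared with processed pseudogenes, with a rho of -0.177 (permutation p = 0.123), stay open.

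Chromosome segments that differ between the lines in copy number or regional expression may account for part of the fold changes. The comparison with the fewest windows past the threshold, Kelly vs SH-SY5Y, had 41, against at most 1 in 20 shuffles of the genes over positions. The test does not part copy number from regional expression. Nor does it part either from a GC-dependent difference, which stays open above, as the GC content of the windows was not examined.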
